A study of Mus musculus with 29 samples.

How the data were processed

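The libraries came from E16.5 mouse cortex treated with vehicle or with the deacetylase inhibitor TSA, from which nuclei were sorted into Tbr2-positive and Tbr2-negative fractions, and each library was assigned to its group from its title alone. The RNA-seq groups held 3 vehicle and 2 TSA libraries per population, and the H3K9ac groups 3 Tbr2-positive vehicle libraries and 4 libraries in each other group. The series describes sorted nuclei, while the protocol text of the RNA samples describes extraction with TRIZOL from whole tissue, and this difference could not be resolved from the descriptions. Eomes, the gene of Tbr2, stood at 443 ± 93.3 CPM in the positive and 18 ± 4.04 CPM in the negative vehicle RNA libraries (n = 3 each). This argues against unsorted tissue, while sorted nuclei and sorted whole cells cannot be told apart by it. No source states that replicates are separate animals, so the p values measure the spread between these samples. The 4 input libraries were not analysed here.

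The RNA values are raw read counts per Ensembl gene, as deposited by the authors, who named SAMtools and the mm10 build, while the aligner, the counting tool and the annotation release are not given in the sources used here. The RNA libraries were made with TruSeq RNA v2 per the labels, a kit that does not keep the strand, so counts of genes that overlap on opposite strands, and of close paralogs, are less certain. Library totals were 18567111 to 26282652 counts, with 22121 to 23924 genes detected. Of 48709 gene identifiers 48349 had a symbol, and symbols and identifiers are given as the files and the reference table give them. The H3K9ac values are peak lists called by the authors with MACS 2.1.0.20140616, per the file headers with a q value threshold of 0.1, duplicates removed, the larger data set scaled towards the smaller and 1 input library per group. The lists hold a pileup at the summit, -log10 p and -log10 q, and a fold enrichment over the local background from the input, all made by MACS per the file headers before the files were deposited. Of these only the peak positions and the -log10 q, as a rank or threshold within a library, were used, because pileup and fold enrichment from separate calls are not on a shared scale. The headers gave 15.2 to 30.3 Mreads of ChIP tags per library, a fragment length of 135 to 157 bp, a bandwidth of 300 and an effective genome size of 1.87e+09. ChIP libraries were made with NEBNext Ultra and a Millipore antibody to H3K9ac per the labels. Peaks per library ranged from 31823 to 82164.

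RNA was tested with edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr (20078), TMM scaling, a robust quasi-likelihood fit of all 10 libraries with 1 mean per group and no covariate, and F tests for 5 contrasts with Benjamini-Hochberg adjustment over all genes of a contrast at 0.05. The median log2 fold change over all genes was -0.04 for TSA in Tbr2-positive and -0.09 in Tbr2-negative nuclei, and no list turned its direction under RLE scaling. The common biological coefficient of variation was 0.374. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM are counts relative to the library total after TMM scaling. A gene without a count in a group is given as a lower bound against 3 counts per library, which covers counting error only. The 23 fixed gene lists were radial glia, basal progenitor, basal radial glia, deep-layer, upper-layer and pan-neuronal, interneuron, Cajal-Retzius, microglia, vascular and meningeal, erythroid, oligodendrocyte precursor, S phase, G2/M phase, p53 target, deacetylase, acetyltransferase, genes induced by deacetylase inhibitors, notch, immediate-early, polycomb, ribosomal protein and mitochondrially encoded genes. They were tested with camera (limma 3.58.1) at the preset correlation of 0.01, adjusted over 115 tests, beside camera with an estimated correlation and fry. The "adjusted over the list alone" counts repeat the Benjamini-Hochberg step within a list.

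Genes named in the text follow a fixed rule: the 8 largest log2 fold changes in each direction among genes that passed, with at least 2 CPM, a symbol that is not a clone name and group ranges that do not overlap; of each list up to 3 passing members with the smallest adjusted p; and always Eomes, Pax6, Sox2, Tbr1, Mki67, Trnp1, Hdac1, Hdac2, Cdkn1a and H1f0. Where fewer than 5 genes passed, the 8 smallest p in each direction were named as not passing, and for the interaction 5 in each direction. In H3K9ac the always-named genes and the genes with the largest RNA changes that passed among those that gained or lost a peak were named. Groups, tests, gene lists, this rule, the H3K9ac window and the main alternatives were set before the data were examined. Some genes that meet this rule are not reported here.

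H3K9ac peaks were compared by presence. The reference table (GRCm38.p6) had no strand, so the planned window around the transcription start became 1 kb on either side of both annotated ends of 21887 protein-coding genes, with an overlap of at least 1 bp. A gene gained or lost a peak when every library of one group and no library of the other had one, and the same count was made over all 35 splits of the libraries. Numbers of peaks, covered length and genes with a peak were compared by exact permutation tests, two-sided as 2 times the smaller tail, adjusted over 12 tests. This form replaced a version based on absolute differences after results had been seen and gives larger p values for groups of 3 and 4 libraries. The interaction was tested by permuting population labels within each treatment, without adjustment over measures and settings. This assumes that the populations differ in neither treatment, so its p values do not test equal TSA effects alone. Lane numbers in the file headers were read as a possible batch, and values within lanes are given beside the pooled ones. RNA changes at genes that gained or lost a peak were compared with 10000 random gene sets matched on mean expression in 20 classes, and by a Fisher exact test.

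In simulated counts with known changes, drawn at the measured dispersions, edgeR recovered 44% of 2-fold and 89% of 4-fold changes for the TSA effect in Tbr2-positive nuclei, 48% and 94% in Tbr2-negative nuclei, and 11% and 72% for the interaction, so small differences between the populations in the TSA effect would mostly be missed. The alternatives tried for RNA were an adjusted p of 0.1, DESeq2 1.42.0, RLE scaling, no low-count filter, the groups of a contrast alone, the replicate number as a block, each library left out and, added after the data were seen, the level of nuclear long noncoding RNA as a covariate and a block for each number within each treatment. For H3K9ac they were a -log10 q of at least 5, lists of equal length (31823 peaks), an overlap of 200 bp, a window of 2 kb, the replicate number as a block and each library left out. The lists of striatal, nuclear long noncoding RNA, further interneuron and respiratory chain genes were added after results had been seen. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots made with matplotlib 3.10.9.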

Results

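Tbr2, the product of Eomes (ENSMUSG00000032446), marks the basal progenitors of the developing mouse cortex, and the comparison of the vehicle libraries addressed which transcripts set the Tbr2-positive nuclei apart from the Tbr2-negative ones at E16.5. Eomes stood at 443 ± 93.3 CPM (mean ± SD, n = 3 libraries) in the positive nuclei and at 18 ± 4.04 CPM (n = 3) in the negative ones, a log2 fold change of 4.62 ± 0.26 (SE; adjusted p = 1.05e-06, edgeR). The proneural gene Neurog1 was higher by a log2 fold change of 4.90 ± 0.57, Neurog2 by 3.89 ± 0.25 and Neurod4, a later step of the same cascade, by 4.99 ± 0.42. Mfap4, a microfibril-associated protein, reached 869 ± 286 CPM against 23.2 ± 7.66 CPM, a 37.4-fold difference. Tac2, which encodes neurokinin B, was 30.1-fold higher, and Sstr2, a somatostatin receptor, 9.12-fold higher. Them5 (4.98 ± 0.77) and Adgrd1 (4.43 ± 0.82) completed the largest positive log2 fold changes together with Lao1, which had no count in the negative libraries and was at least 35.8-fold higher against a floor of 3 counts per library. In the other direction stood Grm4 (-5.22 ± 0.87), Slco4c1 (-5.19 ± 0.91), Slc45a3 (-4.78 ± 0.89), Gpr17 (-4.58 ± 1.27), Rxfp1 (-4.36 ± 1.10), Cdh9 (-3.91 ± 0.52), Adrb1 (-3.78 ± 0.60) and Egfl6 (-3.75 ± 0.93). Without vehicle library 1 of the negative nuclei the call for Gpr17 ended (adjusted p = 0.0807, edgeR), as it did without positive vehicle libraries 1 (0.059) and 3 (0.0575). In all, 1999 genes were higher and 2304 lower in the positive nuclei among 20078 tested (adjusted p below 0.05, edgeR).

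Of the 17 basal progenitor genes, 16 were higher in the positive vehicle nuclei and none was lower, with a median log2 fold change of 2.72 (camera adjusted p = 1.23e-37 with the preset correlation, and adjusted p = 0.126 with an estimated correlation). The cell cycle lists followed the same direction, which fits the known division of basal progenitors in the subventricular zone. Of 20 S-phase genes 18 were higher, Mcm2 among them at 1.64 ± 0.23 and Mcm6 at 1.63 ± 0.24 (19 when adjusted over the list alone; camera adjusted p = 8.42e-14, and adjusted p = 0.188 with an estimated correlation). Of 20 G2/M genes 19 were higher, including Top2a at 1.44 ± 0.19 (20 when adjusted over the list alone; camera adjusted p = 2.5e-16, and adjusted p = 0.222 with an estimated correlation). The proliferation marker Mki67 had a log2 fold change of 1.90 ± 0.31. In the notch list 6 of 14 genes were higher, such as the Notch-modifying Mfng at 2.80 ± 0.31 (7 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.507 with an estimated correlation). The notch call ended without negative vehicle library 2 (camera adjusted p = 0.0592).

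Lists of interneurons, layer neurons, oligodendrocyte precursors and microglia held lower genes in the positive vehicle nuclei. Of the 16 interneuron genes measured 14 were lower, including Erbb4 (-2.86 ± 0.24), Maf and Sst (-2.36 ± 0.24), and all 16 when adjusted over the list alone (camera adjusted p = 1.54e-19, and adjusted p = 0.188 with an estimated correlation). Among 12 deep-layer genes 10 were lower, such as the corticothalamic marker Tle4 (-1.93 ± 0.16), with a median of -0.89 (camera adjusted p = 1.27e-06, and adjusted p = 0.188 with an estimated correlation). Of 11 upper-layer genes 7 were lower and 2 higher, with Mef2c at -2.18 ± 0.28 and Rorb at -1.02 ± 0.18 (camera adjusted p = 0.00774, and adjusted p = 0.509 with an estimated correlation). The upper-layer call ended without positive vehicle library 1 (camera adjusted p = 0.0602). Of the 17 pan-neuronal genes 12 were lower and 1 higher, including Grin2b (-2.52 ± 0.22) and the microtubule protein Mapt (-1.56 ± 0.18; camera adjusted p = 1.37e-07, and adjusted p = 0.309 with an estimated correlation). Of 5 oligodendrocyte precursor genes 4 were lower, among them Cspg4 (-2.79 ± 0.46; camera adjusted p = 0.00145, and adjusted p = 0.188 with an estimated correlation). Of 12 microglial genes 3 were lower, with Cx3cr1 at -1.70 ± 0.37 (5 lower when adjusted over the list alone; camera adjusted p = 0.0323, and adjusted p = 0.562 with an estimated correlation). The microglial call ended without positive vehicle libraries 1 (camera adjusted p = 0.0565) and 3 (0.061) and without negative vehicle libraries 1 (0.0594) and 3 (0.0606).

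Some genes of the deacetylases, the targets of the inhibitor TSA, differed in RNA between the populations in vehicle, in both directions. Hdac9, which encodes a class IIa enzyme, stood at 97.3 ± 9.18 CPM in the positive and 19.8 ± 3.04 CPM in the negative vehicle nuclei (n = 3 each), 4.92-fold higher (adjusted p = 8.41e-06, edgeR). Hdac1 was also higher, at 85.4 ± 10.6 against 38.2 ± 3.94 CPM (log2 fold change 1.16 ± 0.16), while Hdac11 was lower at -1.55 ± 0.23. Hdac2 was higher by 0.45 ± 0.14 (adjusted p = 0.0381, edgeR), a call that ended without negative vehicle libraries 1 (0.128) and 3 (0.064) and without positive vehicle libraries 2 (0.127) and 3 (0.0805). Of the 11 deacetylase genes 5 were higher and 1 lower (5 and 2 when adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0276, and adjusted p = 0.426 with an estimated correlation). That call ended without negative vehicle libraries 2 (camera adjusted p = 0.0561) and 3 (0.0677). H1f0, a linker histone gene known to respond to deacetylase inhibitors, was higher by 1.74 ± 0.14. The acetyltransferase list had 1 gene of 10 higher, Kat6b at 0.99 ± 0.17. Its camera test did not pass (adjusted p = 0.341), while fry gave an adjusted p of 0.0488.

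The lists named above as passing camera in vehicle also passed fry (fry adjusted p = 0.00167 to 0.0245). The other fixed lists did not pass camera in the vehicle libraries. Of those below, fry passed the basal radial glial (fry adjusted p = 0.00438), p53 target (0.0197) and polycomb lists (0.00312). Of 24 radial glial genes 8 were higher and 2 lower, with Pax6 at 1.72 ± 0.22, Tfap2c at 2.53 ± 0.26 and Ptprz1 at -1.74 ± 0.16 (camera adjusted p = 0.0678; 9 and 5 when adjusted over the list alone). The basal radial glial list of 8 genes had a median of -0.98 and a mean of 0.06, so its direction depended on the summary (camera adjusted p = 0.0889). Within it Fam107a, without a count in the negative vehicle libraries, was at least 8.35-fold higher, a call that ended without positive vehicle library 3 (adjusted p = 0.0664, edgeR). Trnp1, a nuclear protein gene linked to cortical expansion, was lower in the positive nuclei at 2.74 ± 0.309 against 10.2 ± 3.52 CPM (log2 fold change -1.89 ± 0.37; adjusted p = 0.00271, edgeR). Sox2 (0.08 ± 0.18), Tbr1 (0.03 ± 0.19) and Cdkn1a (-0.32 ± 0.23) did not pass (adjusted p = 0.819, 0.943 and 0.382, edgeR). The p53 target list split into 3 higher and 2 lower of 14, with Trp53inp1 at 1.93 ± 0.18 and Plk2 at -1.79 ± 0.25 (camera adjusted p = 0.251). The list of genes known to rise under deacetylase inhibitors had 2 higher and 1 lower of 10, with H1f0 higher and Clu lower at -1.36 ± 0.26 (camera adjusted p = 0.334). Polycomb genes had 4 higher of 13, including Ezh2 (camera adjusted p = 0.113). Immediate-early genes had 2 higher of 14, including Ier2 at 2.16 ± 0.26 (camera adjusted p = 0.682). Cajal-Retzius genes had 2 higher and 1 lower of 9, with Nhlh2 at 1.76 ± 0.29 (camera adjusted p = 0.716). Ribosomal protein genes had 3 lower of 76, with Rpl12 at -0.79 ± 0.17 (camera adjusted p = 0.191). The vascular and meningeal list had 1 lower of 16, Dcn (camera adjusted p = 0.637). Erythroid (8 genes) and mitochondrially encoded transcripts (7 genes) had 0 called genes (camera adjusted p = 0.445 and 0.751).

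**Figure D1:**
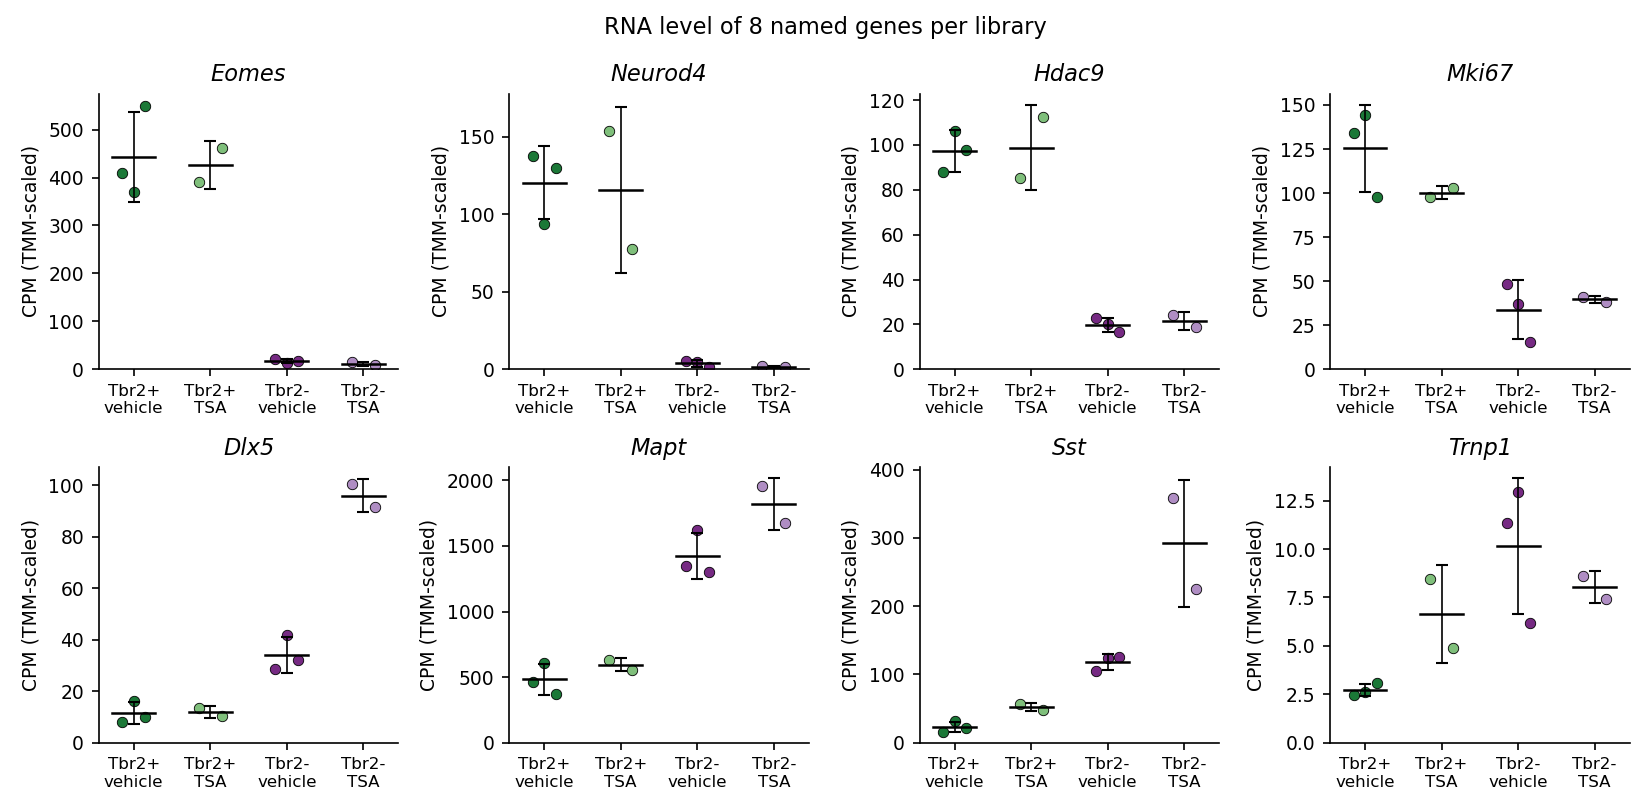
Expression of Eomes, Neurod4, Hdac9, Mki67, Dlx5, Mapt, Sst and Trnp1 in CPM scaled by TMM, with points for libraries (n = 3 vehicle and n = 2 TSA per population), lines for means and bars for SD. Mean Sst was 119 CPM in vehicle and 292 CPM in TSA in the Tbr2-negative nuclei.

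The effect of TSA in the Tbr2-positive nuclei addressed whether the inhibitor changed transcription in basal progenitors. No gene passed an adjusted p of 0.05 with edgeR, while 3175 genes had an unadjusted p below 0.05 where chance alone would give 1004. DESeq2 called 1015 genes on the same counts, edgeR without the low-count filter 364, and edgeR called 3 genes without positive vehicle library 3 and 39 without positive TSA library 2. The smallest p values in the downward direction belonged to Cwc22 (ENSMUSG00000027014), a spliceosome factor, at 335 ± 64.6 CPM in vehicle and 3.2-fold lower in TSA (log2 fold change -1.68 ± 0.22; n = 3 and 2; adjusted p = 0.0529, edgeR). Slc38a10 (-1.34 ± 0.19), Masp1 (-1.36 ± 0.21), the axon guidance receptor Dcc (-1.47 ± 0.26), Sema4c (-1.76 ± 0.32), Col9a3 (-1.41 ± 0.26), Leng8 and Phkg2 also did not pass (adjusted p = 0.056 to 0.0948, edgeR). Upward, mt-Rnr1, the mitochondrial ribosomal RNA, stood at 30.0 ± 8.07 against 99.6 ± 18.2 CPM (1.73 ± 0.24; adjusted p = 0.0529, edgeR). Ppp2r2c (1.34 ± 0.21), Tmsb10 (1.32 ± 0.23), Rps12 (1.31 ± 0.22), Rpl12 (1.11 ± 0.19), Pfdn4, Mmd and the reelin receptor gene Vldlr (0.93 ± 0.15) followed without passing (adjusted p = 0.0819 to 0.0948, edgeR). Eomes itself, whose product was the sorting marker, had a log2 fold change of -0.05 ± 0.24 (adjusted p = 0.946, edgeR). Trnp1 stood at 6.66 ± 2.52 CPM in TSA (1.28 ± 0.40; adjusted p = 0.152, edgeR) and Cdkn1a, which encodes the cell cycle inhibitor p21, at 0.75 ± 0.26 (adjusted p = 0.183, edgeR), neither passing. Mki67 (-0.32 ± 0.34), Pax6, Sox2, Tbr1, Hdac1, Hdac2 and H1f0 had adjusted p values of 0.539 or more (edgeR).

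Of 76 ribosomal protein genes measured in the TSA-treated positive nuclei, 0 passed over all genes and 75 had a positive log2 fold change with a median of 0.82, and their summed level went from 8646 ± 1680 to 14870 ± 1400 CPM (n = 3 and 2). The camera test passed with the preset correlation (adjusted p = 6.33e-56), and fry gave an adjusted p of 0.0401, but camera gave adjusted p = 0.26 with an estimated correlation. When adjusted over the list alone 70 of the 76 passed as higher. Long noncoding RNAs that stay in the nucleus, such as Malat1 (-0.40) and Neat1, had a median of -0.66 in the same libraries, with 3 of 10 positive and none passing alone. All 17 pan-neuronal genes had positive values with a median of 0.38 (4 rose when adjusted over the list alone; camera adjusted p = 8.14e-07, and adjusted p = 0.309 with an estimated correlation). Deep-layer genes had a median of 0.25 (2 of 12 rose when adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.456 with an estimated correlation). Upper-layer genes were positive for 9 of 11 (0 when adjusted over the list alone; camera adjusted p = 0.0211, and adjusted p = 0.562 with an estimated correlation). The 5 oligodendrocyte precursor genes, summed at 10.2 ± 3.1 CPM in vehicle and 19.2 ± 1.3 CPM in TSA, were all positive with a median of 1.14 (camera adjusted p = 0.0224, and adjusted p = 0.309 with an estimated correlation). With fry the pan-neuronal (fry adjusted p = 0.0488) and precursor lists (0.0439) passed, while the deep-layer (0.17) and upper-layer lists (0.272) did not. The upper-layer call ended without positive vehicle libraries 1 (camera adjusted p = 0.0945) and 3 (0.0785) and positive TSA library 2 (0.146). The precursor call ended without positive vehicle library 1 (0.0602), and the deep-layer call without positive vehicle library 3 (0.0681) and positive TSA library 2 (0.156; camera adjusted p).

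The remaining lists did not pass camera in the positive nuclei. Basal progenitor genes, positive for 3 of 17, had a median of -0.21 (camera adjusted p = 0.441), and radial glial genes a median of 0.01 (camera adjusted p = 0.971). S-phase and G2/M genes had medians of 0.17 and -0.06 (camera adjusted p = 0.687 and 0.929). Deacetylase genes had a median of -0.23 (camera adjusted p = 0.18). The genes known to rise under deacetylase inhibitors were positive for 8 of 10 with a median of 0.48 (camera adjusted p = 0.264). Interneuron and Cajal-Retzius genes shared a median of 0.31 (camera adjusted p = 0.0652 and 0.0828). Erythroid genes had a median of 0.05 and a mean of -0.51, so their direction depended on the summary (camera adjusted p = 0.751). Mitochondrially encoded transcripts, a marker of RNA handling and sample quality, were positive for 5 of 7 with a median of 0.76 (camera adjusted p = 0.1). The percentage of counts on all genes with a mitochondrial symbol, which include others such as mt-Rnr1, was 0.0979 to 0.306 in the positive vehicle libraries and 0.306 to 0.328 in the positive TSA libraries.

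In the Tbr2-negative nuclei the same question gave 164 genes that rose and 72 that fell (edgeR, smallest adjusted p = 0.0481). Tmsb10, a thymosin that binds actin monomers, rose from 219 ± 48.4 to 633 ± 103 CPM (log2 fold change 1.53 ± 0.23; n = 3 and 2), and Tmsb4x rose by 1.33 ± 0.25. The interneuron transcription factor Dlx5 (ENSMUSG00000029755) rose from 34.2 ± 6.91 to 95.9 ± 6.29 CPM (1.49 ± 0.27), and the neuropeptide gene Sst from 119 ± 11.7 to 292 ± 93.5 CPM (1.30 ± 0.25). Isl1, a transcription factor of striatal and motor neurons, rose by 1.46 ± 0.30 and Zic1, a factor of the septum and medial forebrain, by 1.37 ± 0.28. Further rises were mt-Rnr1 (1.38 ± 0.24), Rnf11 (1.35 ± 0.21), and the ribosomal Rps29 (1.34 ± 0.21), Rpl32 (1.29 ± 0.24) and Rpl38 (1.29 ± 0.22). Sox2 rose from 27.0 ± 3.77 to 56.5 ± 1.66 CPM. Syt2, a synaptic vesicle calcium sensor, fell from 3.97 ± 1.33 to 0.230 ± 0.0884 CPM (-4.08 ± 0.76). Cwc22 fell from 280 ± 58.8 to 92.8 ± 3.67 CPM (-1.59 ± 0.22). Grip2 (-1.58 ± 0.28), the incretin receptor gene Gipr (-1.41 ± 0.25), the lipid synthesis regulator Srebf1 (-1.36 ± 0.25), Zfp692 (-1.35 ± 0.24), Spata1 (-1.44 ± 0.29) and BC022960 (-1.43 ± 0.30) fell as well. All adjusted p values of the genes named as changed here were 0.0481 or 0.0482 (edgeR), and no call of any gene remained without negative TSA libraries 1 or 2, negative vehicle libraries 1 or 3, or positive vehicle library 2 (0 genes each). The count was 386 without positive vehicle library 1, 516 without positive TSA library 1 and 677 without negative vehicle library 2, while DESeq2 called 2001 genes and edgeR 0 with the level of nuclear long noncoding RNA as a covariate.

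Cdkn1a (0.94 ± 0.26; adjusted p = 0.0717, edgeR), H1f0 (0.51 ± 0.15; 0.0877), Hdac2 (0.45 ± 0.16; 0.128), Eomes (-0.69 ± 0.26; 0.163), Tbr1, Mki67, Pax6, Hdac1 and Trnp1 (-0.34 ± 0.40; 0.685) did not pass in the negative nuclei. Of 76 ribosomal protein genes 21 rose and 75 were positive, with a median of 0.83 and a summed level of 9518 ± 1750 CPM in vehicle against 16420 ± 2840 CPM in TSA. Over that list alone 68 rose (camera adjusted p = 8.97e-47, fry adjusted p = 0.0431, and camera adjusted p = 0.309 with an estimated correlation). Nuclear long noncoding RNAs had a median of -0.77 beside them, with 2 of 10 positive. All 16 interneuron genes were positive with a median of 0.67, and their summed level went from 943 ± 73.0 to 1560 ± 54.4 CPM (2 rose over all genes and 6 when adjusted over the list alone; camera adjusted p = 7.73e-08, and adjusted p = 0.362 with an estimated correlation). Markers of striatal neurons had a median of 0.43 in the same libraries, with 9 of 12 positive. Pan-neuronal genes had a median of 0.28 (2 of 17 rose when adjusted over the list alone; camera adjusted p = 0.0046, and adjusted p = 0.562 with an estimated correlation). Radial glial genes, with Sox2 as the only call and 4 when adjusted over the list alone, had a median of 0.29 (camera adjusted p = 0.0323, and adjusted p = 0.602 with an estimated correlation). Genes known to rise under deacetylase inhibitors were positive for 8 of 10 (0 called over all genes and 2 when adjusted over the list alone; camera adjusted p = 0.0323, and adjusted p = 0.562 with an estimated correlation). Mitochondrially encoded transcripts were positive for 6 of 7 with a median of 0.90 (camera adjusted p = 0.0323, and adjusted p = 0.723 with an estimated correlation). The percentage of counts on all genes with a mitochondrial symbol was 0.114 to 0.283 in vehicle and 0.323 to 0.445 in TSA. With fry the interneuron (fry adjusted p = 0.0769), pan-neuronal (0.17), radial glial (0.294), inhibitor (0.17) and mitochondrial lists (0.537) did not pass. The radial glial call ended without negative vehicle libraries 2 (camera adjusted p = 0.2) and 3 (0.0967) and negative TSA library 2 (0.212). The inhibitor list call ended without negative vehicle libraries 2 (0.0765) and 3 (0.0715) and negative TSA library 1 (0.147), and the mitochondrial call without negative vehicle library 1 (0.385; camera adjusted p).

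The lists that did not pass camera in the negative nuclei included basal progenitor genes, with 4 of 17 positive and a median of -0.30 (camera adjusted p = 0.239), deep-layer genes (median 0.23, camera adjusted p = 0.124) and Cajal-Retzius genes (0.54, camera adjusted p = 0.0678). Upper-layer genes had a median of 0.09 and a mean of -0.09, and basal radial glial genes a median of -0.18 and a mean of 0.76 (camera adjusted p = 0.833 and 0.813). S-phase and G2/M genes had medians of 0.05 and 0.09 (camera adjusted p = 0.26 and 0.665). Oligodendrocyte precursor genes summed to 44.9 ± 9.37 CPM in vehicle and 66.0 ± 0.537 CPM in TSA (median 0.56, camera adjusted p = 0.267). Microglial genes summed to 59.7 and 73.1 CPM (camera adjusted p = 0.334). Erythroid genes had a median of -0.10 and vascular genes of -0.43 (camera adjusted p = 0.687 and 0.652).

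**Figure D2:**
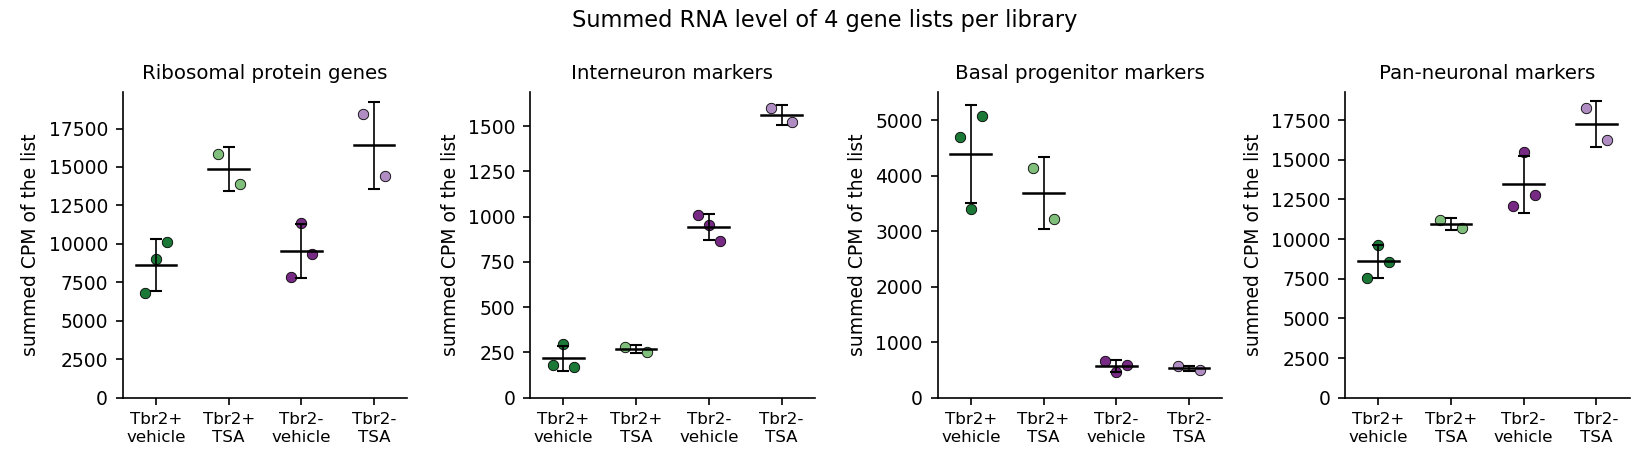
Summed expression in CPM of the ribosomal protein, interneuron, basal progenitor and pan-neuronal lists, with points for libraries (n = 3 vehicle and n = 2 TSA per population), lines for means and bars for SD. The interneuron sum was 943 CPM in vehicle and 1560 CPM in TSA in the Tbr2-negative nuclei.

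Whether TSA acted differently in the populations was addressed by the interaction. Laptm4b (difference in log2 fold change -1.69 ± 0.33) and Rbms3 (-1.66 ± 0.32) had an adjusted p of 0.634, the smallest found (edgeR), and did not pass. Vldlr, Prickle2, Coq2, Dvl1, Glyr1, Glb1l2 and Spryd3 had adjusted p values of 0.826 or 0.895 (edgeR). Trnp1 had a difference of 1.62 ± 0.57, Sox2 of -0.87 ± 0.29 and H1f0 of -0.70 ± 0.22 (adjusted p = 0.895 each, edgeR). Eomes (0.64 ± 0.36; adjusted p = 0.897, edgeR), Mki67, Hdac2, Pax6, Cdkn1a, Hdac1 and Tbr1 did not pass either. The edgeR count was 0 genes, with 1103 at an unadjusted p below 0.05 against 1004 by chance, and DESeq2 called 11. Interneuron genes had a median difference of -0.40, with 3 of 16 positive (camera adjusted p = 0.000846, and adjusted p = 0.602 with an estimated correlation). Radial glial genes had -0.31 with 5 of 24 positive (camera adjusted p = 0.0276, and adjusted p = 0.602 with an estimated correlation). Upper-layer genes had 0.33 with 8 of 11 positive (camera adjusted p = 0.0493, and adjusted p = 0.602 with an estimated correlation). With fry the interneuron (fry adjusted p = 0.474), radial glial (0.474) and upper-layer lists (0.477) did not pass. The ribosomal protein genes had a median difference of -0.04 (camera adjusted p = 0.968). The interneuron call ended without positive vehicle library 2 (camera adjusted p = 0.282). The radial glial call ended without positive vehicle library 3 (0.14), positive TSA library 2 (0.265), negative vehicle libraries 2 (0.15) and 3 (0.0933) and negative TSA library 2 (0.194; camera adjusted p). The upper-layer call ended without positive vehicle libraries 1 (0.262) and 3 (0.0757), positive TSA library 2 (0.197), negative vehicle library 2 (0.2) and negative TSA library 2 (0.25; camera adjusted p). Across 10392 genes with at least 10 CPM the TSA effects in the populations correlated at r = 0.644 (Pearson), and 228 of the 236 genes called in the negative nuclei had the same sign in the positive ones (96.6%, against 67.2% of all genes). If both populations were sorted from the same samples, which the labels do not state, differences between samples would enter both effects. The 5 same-number pairs of both populations within a treatment correlated at 0.081 to 0.117. This likeness is therefore no independent replication.

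In the TSA libraries the comparison of the populations addressed which transcripts set them apart under the inhibitor. The nuclei were sorted by Tbr2, so a higher Eomes level in the positive fraction follows from the sort. A nucleus that lost Tbr2 would fall into the negative fraction. These values therefore cannot show whether the identity of basal progenitors held. Eomes stood at 427 ± 50.3 CPM against 11.2 ± 4.19 CPM (log2 fold change 5.25 ± 0.32; n = 2 each; adjusted p = 1.19e-05, edgeR), Neurod4 was 69.1-fold, Neurog1 64.2-fold and Neurog2 17.0-fold higher. Lingo4 (5.87 ± 1.11), Them5 (5.73 ± 0.97), the pseudogene Spr-ps1 (5.63 ± 0.78), Dtx3l (5.4 ± 1.06) and Gfap (4.99 ± 0.92) completed the largest positive log2 fold changes. The largest negative ones were Tmem132d (-4.46 ± 0.92), Dock10 (-4.15 ± 0.77), Aldh1a3 (-4.10 ± 0.71), Trhr (-4.06 ± 0.54), Glb1l2 (-3.98 ± 0.76), Htr1f (-3.96 ± 0.66), the interneuron factor Dlx6 (-3.32 ± 0.55) and the GABA transporter gene Slc32a1 (-3.30 ± 0.60). Dtx3l (0.0783) and Lingo4 (0.0675) lost their calls without negative TSA library 1, Tmem132d without negative TSA library 2 (0.0897) and positive TSA library 1 (0.0764), and Glb1l2 without positive TSA library 1 (0.0514; adjusted p, edgeR). Hdac9 was 4.60-fold higher at 98.9 ± 19 against 21.5 ± 4 CPM, Hdac1 was higher (1.11 ± 0.19) and Hdac11 lower (-1.86 ± 0.28). Pax6 (1.52 ± 0.27) and H1f0 (1.04 ± 0.17) were higher. Mki67 was higher at 1.34 ± 0.37 (adjusted p = 0.0409, edgeR), a call that ended without negative TSA libraries 1 (0.16) and 2 (0.165), negative vehicle library 2 (0.0542) and positive TSA libraries 1 (0.101) and 2 (0.115). Sox2 was lower at -0.79 ± 0.23 (0.0452), a call that ended without any library of the TSA groups (negative 0.237 and 0.144, positive 0.24 and 0.0712), negative vehicle libraries 1 (0.0557) and 3 (0.0675) and positive vehicle libraries 1 (0.0642) and 2 (0.0606; adjusted p, edgeR). Hdac2 (adjusted p = 0.521), Trnp1 (0.788), Tbr1 (0.97) and Cdkn1a (0.324; edgeR) did not pass. In all 841 genes were higher and 1030 lower (1871 together; edgeR), and the count was 1071 and 1203 without positive TSA libraries 1 and 2 and 683 and 968 without negative TSA libraries 1 and 2.

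Of 17 basal progenitor genes 15 were higher in the TSA libraries (16 when adjusted over the list alone; camera adjusted p = 3.36e-47, and adjusted p = 0.109 with an estimated correlation). Of 20 S-phase genes 15 were higher (17 when adjusted over the list alone), such as Ccne2 at 1.65 ± 0.25 (camera adjusted p = 2.86e-14, and adjusted p = 0.188 with an estimated correlation). Of 20 G2/M genes 15 were higher (20 when adjusted over the list alone), including Ccnb2 at 1.94 ± 0.32 (camera adjusted p = 1.97e-17, and adjusted p = 0.188 with an estimated correlation). Of 16 interneuron genes 15 were lower, including Dlx5 (-3.00 ± 0.33) and Erbb4 (-2.84 ± 0.30), with a median of -2.65 (camera adjusted p = 1.04e-35, and adjusted p = 0.126 with an estimated correlation). Of 12 deep-layer genes 5 were lower, including Hs3st4 (-2.66 ± 0.39), and 10 when adjusted over the list alone (camera adjusted p = 6.14e-07, and adjusted p = 0.188 with an estimated correlation). Of 17 pan-neuronal genes 8 were lower and 1 higher, including Mapt (-1.62 ± 0.23; camera adjusted p = 1.12e-06, and adjusted p = 0.315 with an estimated correlation). Of 5 oligodendrocyte precursor genes 3 were lower, with Olig1 at -2.38 ± 0.42 (camera adjusted p = 0.00394, and adjusted p = 0.222 with an estimated correlation). Of 12 microglial genes 4 were lower, with Cx3cr1 at -3.06 ± 0.48 (camera adjusted p = 0.001, and adjusted p = 0.345 with an estimated correlation). Of 8 basal radial glial genes 2 were lower, with Ptprz1 at -1.35 ± 0.19 (camera adjusted p = 0.0081, and adjusted p = 0.188 with an estimated correlation). Of 14 notch genes 4 were higher, including Mfng at 2.98 ± 0.38 (6 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.512 with an estimated correlation). The basal radial glial call ended without positive TSA library 2 (camera adjusted p = 0.0569) and the notch call without positive TSA library 1 (0.055; camera adjusted p). Upper-layer (camera adjusted p = 0.119), radial glial (0.687) and deacetylase genes (0.192; camera adjusted p) did not pass. With fry the notch list did not pass (fry adjusted p = 0.0769), while the other lists that passed camera here did (0.00241 to 0.0258).

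H3K9 acetylation marks active promoters and enhancers and is removed by the enzymes that TSA inhibits, so the peak lists addressed whether the acetylated regions changed in number and place. In the Tbr2-positive nuclei the libraries held 69049 ± 11402 peaks in vehicle (n = 3) and 34820 ± 3610 in TSA (n = 4), 50.4% of the vehicle mean, and the ranges did not overlap (exact permutation p = 0.0571, two-sided, the smallest possible with these libraries; 0.114 adjusted over 12 tests). Within lane 1 the vehicle library had 82164 peaks and the TSA libraries 34045 and 40053, and within lane 2 the vehicle libraries had 61487 and 63496 and the TSA library 33359. The covered length went from 31.4 ± 1.88 to 19.9 ± 0.993 Mb (exact permutation p = 0.0571, the smallest possible). Genes with a peak within 1 kb of either annotated end numbered 13943 ± 194 in vehicle and 12654 ± 119 in TSA, a difference of -1290 (exact permutation p = 0.0571, the smallest possible). Peaks at gene ends numbered 20760 in vehicle and 18290 in TSA, while peaks elsewhere numbered 48289 ± 10290 and 16530 ± 3002. The share of peaks at gene ends was therefore 30.4 ± 3.19% in vehicle and 52.8 ± 3.50% in TSA, but 51.7 ± 0.798% and 55.7 ± 0.49% with lists of equal length, so most of that difference followed list length. With the vehicle peaks of each library ranked by q into 4 classes, 99.5 ± 0.706% of the strongest class overlapped a TSA peak and 17.2 ± 3.36% of the weakest class. This share depends on the length of the TSA lists: against TSA lists of equal length the weakest class was at 14.3 ± 2.82% in positive and 19 ± 3.2% in negative nuclei. Eomes (chromosome 9, 118478186 to 118486132, mm10), Pax6, Sox2, Tbr1, Mki67, Hdac1, Hdac2 and H1f0 kept a peak at an end in every library of every group, except that with lists of equal length Eomes had one in 3 and Pax6 in 2 of 4 negative TSA libraries. Trnp1 and Cdkn1a had a peak in none of the positive libraries.

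**Figure D3:**
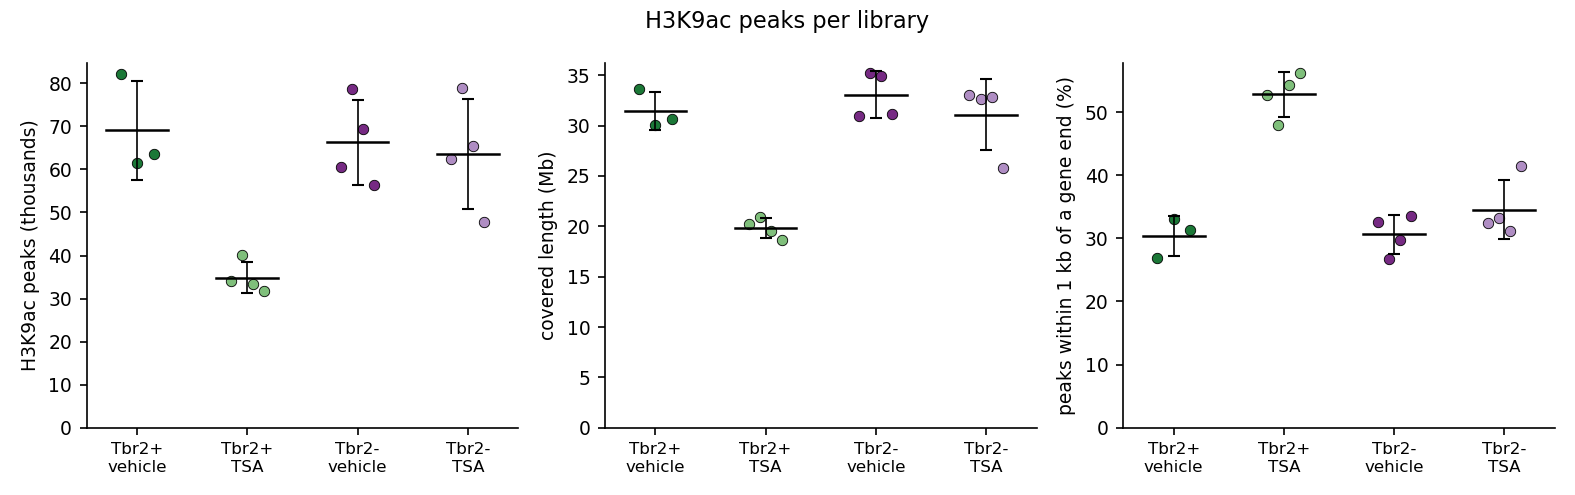
H3K9ac peaks per library (axis in units of 1000 peaks), covered length in Mb and the percentage of peaks within 1 kb of a gene end, with points for libraries (n = 3 Tbr2-positive vehicle and n = 4 in each other group), lines for means and bars for SD. Mean peaks were 69049 in Tbr2-positive vehicle and 34820 in Tbr2-positive TSA, and the percentage depends on the length of the lists.

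At gene ends, 231 genes had a peak in every vehicle library and in no TSA library of the positive nuclei, while 1 gene had the opposite pattern and 11990 kept a peak in all libraries. With lists of equal length (31823 strongest peaks per library) the counts were 24 and 7, and with a -log10 q of at least 5 they were 115 and 1, with 15 of the 232 genes found again in either case. In the Tbr2-negative nuclei the libraries held 66273 ± 9907 peaks in vehicle and 63621 ± 12758 in TSA (n = 4 each; exact permutation p = 0.8, smallest possible 0.0286), and covered 33.0 ± 2.33 and 31.1 ± 3.51 Mb (exact permutation p = 0.371). Genes with a peak at an end numbered 14105 ± 172 and 13852 ± 261 (exact permutation p = 0.2). Within lane 1 the negative vehicle libraries had 60637 and 78773 peaks and the TSA library 62329, within lane 2 69280 against 65390 and 78929, and within lane 3 56403 against 47835. There 6 genes lost and 2 gained a peak at an end, against 10 and 5 with lists of equal length and 9 and 6 with a -log10 q of at least 5. Of the weakest class of vehicle peaks 43.5% overlapped a peak of the longer TSA lists in the negative nuclei. The difference between the TSA effects in the populations was -31576 peaks (permutation p = 0.0269, over 2450 permutations), -9.62 Mb (permutation p = 0.0539) and -1037 genes (permutation p = 0.0318). These p values were not adjusted, and they assume that the populations differ in neither treatment, so they do not test equal TSA effects alone. With lists of equal length the genes with a peak differed by -271 in positive and -294 in negative nuclei, leaving a difference between the effects of 23 (permutation p = 0.996), and the difference in covered length was -2.86 Mb (permutation p = 0.244). With a -log10 q of at least 5 the differences between the effects were -9282 peaks (permutation p = 0.0131), -5.14 Mb (permutation p = 0.0857) and -644 genes (permutation p = 0.153).

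**Figure D4:**
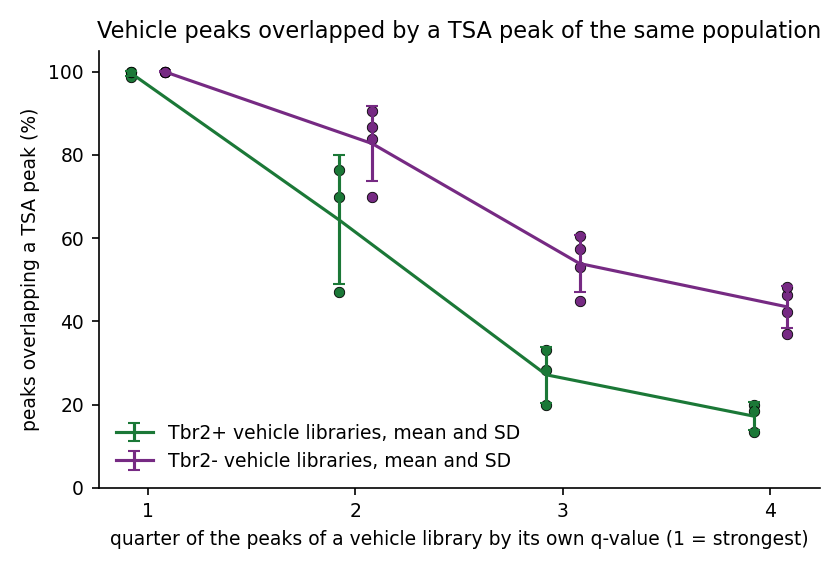
Percentage of vehicle H3K9ac peaks that overlapped a TSA peak of the same population, in 4 classes of the vehicle peaks ranked by q within each library (1 = strongest), with points for libraries, lines for means and bars for SD (n = 3 Tbr2-positive and n = 4 Tbr2-negative vehicle libraries). The weakest class was at 17.2% in Tbr2-positive and 43.5% in Tbr2-negative nuclei, a share that depends on the length of the TSA lists (14.3% and 19% against TSA lists of equal length).

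Between the populations, the peak lists addressed which genes carried the mark in basal progenitors. In vehicle, peaks differed by 2776 (exact permutation p = 0.743), covered length by -1.60 Mb (exact permutation p = 0.286) and genes with a peak at an end by -162 (exact permutation p = 0.343; smallest possible 0.0571 in each). In TSA the positive nuclei differed by -28801 peaks, -11.22 Mb of covered length and -1199 genes (exact permutation p = 0.0286 each, the smallest possible; 0.114 adjusted over 12 tests). Within lane 3 the TSA libraries had 31823 peaks in the positive and 47835 in the negative nuclei. Neurod4 (chromosome 10, 130268152 to 130280254, mm10) had a peak in all 3 positive vehicle and all 4 positive TSA libraries and in 0 of 8 negative ones. The interneuron genes Slc32a1 and Gad1 had a peak in 1 of 3 positive vehicle libraries, in 0 of 4 positive TSA libraries and in all 8 negative ones. Trnp1 had a peak in 2 of 4 negative vehicle libraries only. In vehicle 92 genes had a peak in every negative library and no positive one, and 22 the reverse, against 194 and 20 with lists of equal length. In TSA these counts were 295 and 1, against 133 and 10 with lists of equal length, where Gad1, Slc32a1 and Wnt4 were found again. Of 16 interneuron genes, 10.7 ± 0.577 had a peak at an end in positive and 15 ± 1.15 in negative vehicle libraries (exact permutation p = 0.0571, the smallest possible), and 9.25 ± 0.5 and 15.2 ± 0.5 in TSA (exact permutation p = 0.0286, the smallest possible; the smallest of 88 list tests adjusted together was 0.359).

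Whether transcription followed the acetylation at gene ends was addressed by joining the assays. In vehicle, 19 of the 58 measured genes with a peak in every negative and no positive library were also lower in RNA of the positive nuclei, with Fgf3 (1.5 ± 0.347 CPM in negative and 0 CPM in positive vehicle nuclei; adjusted p = 0.00151, edgeR), Kcns2 (-3.95 ± 1.14; 0.0253), Slc26a7 (-3.04 ± 0.54; 0.00143) and Wnt4 (-2.98 ± 0.73; 0.0104) among the largest changes. The morphogen gene Ihh, with peaks in 0 of 3 positive and 4 of 4 negative vehicle libraries, went the other way at 0.772 ± 0.534 CPM in positive and 0 CPM in negative nuclei (adjusted p = 0.0335, edgeR), as did Bhlhe23 (4.27 ± 1.37), Pxylp1 (1.58 ± 0.22) and Plch2 (1.43 ± 0.27). With lists of equal length Ihh, Fgf3, Kcns2 and Wnt4 kept the peak in 4 of 4 negative vehicle libraries. Slc26a7 had it in 3, and Bhlhe23, Pxylp1 and Plch2 in 0, so Slc26a7, Bhlhe23, Pxylp1 and Plch2 no longer belonged to the set. The 58 genes had a median log2 fold change of -1.44 (permutation p = 0.0001 against 10000 random gene sets matched on expression, the smallest possible). RNA was called higher for 4 of the 58 genes, and the 19 lower ones made up 32.8% against 13.6% of the genes that kept their peaks (Fisher exact p = 0.000156, across genes that are not independent replicates). In TSA the largest RNA changes among such genes were those of Tmem132d (-4.46 ± 0.92), Slc32a1 (-3.30 ± 0.60), Galnt9 (-3.15 ± 0.46), Sp9 (-3.09 ± 0.39) and Gad1 (-2.70 ± 0.36), of which Tmem132d kept the peak in 3 and Sp9 in 2 of 4 negative TSA libraries with lists of equal length. The 184 measured had a median of -1.35 (permutation p = 0.0001, the smallest possible), and RNA was called lower for 29, or 15.8% against 6.24% (Fisher exact p = 5.41e-06). The genes gained in positive vehicle nuclei, 14 of them measured, had a median of 0.16 (permutation p = 0.278 against matched sets) and 2 called higher. With lists of equal length 16 such genes were measured, with a median of 0.80 (permutation p = 0.0006) and 8 called higher, or 50% against 14.1% (Fisher exact p = 0.000712), and with a -log10 q of at least 5 the median was 0.42 (permutation p = 0.0452). For the TSA effect in the positive nuclei, 120 of the 231 genes that lost a peak were measured, with a median of -0.16 against -0.14 in matched sets (permutation p = 0.771), and the median turned to 0.22 with lists of equal length (permutation p = 0.162) and 0.006 with a -log10 q of at least 5 (permutation p = 0.242).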

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

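The tests of nuclear long noncoding RNA, striatal markers, gene span, peak depth, list length, input libraries and splits were chosen only after the result was seen; the criteria for the covariate and for further interneuron markers were written before those values were computed, though after the patterns they address had been seen.

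Tbr2-negative TSA library 4 stood apart in H3K9ac, with a covered length of 25.8 Mb where the next library had 32.7 Mb (gap over range 0.95), and with 15.2 Mreads of ChIP tags where the next had 22.2 Mreads (0.889). Both exceeded the 95% critical value of Dixon's test for 4 libraries, in 12 such tests, and chance marks about 1 in 20 groups. The other results singled out were differences between the populations in the TSA effect. They were -31576 peaks (permutation p = 0.0269, not adjusted) and -1037 genes with a peak at a gene end (permutation p = 0.0318, not adjusted, and 23 genes with lists of equal length, permutation p = 0.996). Median log2 differences of -0.31 in radial glial, 0.33 in upper-layer and -0.40 in interneuron genes were singled out by camera with the preset correlation. None of these lists passed with an estimated correlation (camera adjusted p = 0.602 each), and each call ended when certain single libraries were left out.

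The smaller number of peaks in TSA, seen in Tbr2-positive but not in Tbr2-negative nuclei, could come from a smaller depth after scaling to the input, from longer lists of weak peaks in the vehicle libraries, or from the input library. The Tbr2-positive TSA libraries were all scaled down to an input of 20.1 Mreads, against depths of 27.6 to 29.5 Mreads in Tbr2-positive vehicle. The Tbr2-negative TSA library with the fewest tags, 15.2 Mreads, still held 47835 peaks, more than the 40053 of the fullest Tbr2-positive TSA library. That is 1 library of the other population, called against another input. It cannot decide whether depth caused the difference within the Tbr2-positive nuclei. With lists of equal length 31 gene ends gained or lost a peak, against 26 in the most different other split, so much of the count of 232 with full lists could follow list length. With a -log10 q of at least 5 the Tbr2-positive TSA libraries held at most 25738 peaks and the vehicle libraries at least 31629. A q value depends on the depth of the call, which was smaller in these TSA libraries. The threshold therefore cannot separate weak peaks from depth. At equal length the covered length still lay apart (18.6 to 19.8 Mb in TSA, 23.6 to 24.2 Mb in vehicle), but each group had only 1 input library, so an effect of TSA and an effect of that input cannot be told apart. Over the 35 splits of the libraries, the true grouping alone gave 232 gene ends (1 split, highest other 84, and 116 against 61 with the q threshold). This argues against chance as the source of that count. It does not exclude chance, as 1 of 35 is the smallest share possible and was not adjusted over comparisons. A technical difference between the groups is not excluded either.

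The mostly positive log2 fold changes of ribosomal protein genes in both populations could reflect less nuclear and more cytoplasmic RNA in the TSA libraries, short genes that were counted more fully, or a response to the inhibitor. Nuclear long noncoding RNAs had a median log2 fold change of -0.77 in Tbr2-negative and -0.66 in Tbr2-positive nuclei (camera adjusted p = 0.00694 and 0.0428, and adjusted p = 0.293 and 0.366 with an estimated correlation), and Neat1 stood at -1.89 and -1.54 without passing. Tbr2-positive TSA library 2 had 12120 CPM of these RNAs, within the vehicle range of 10410 to 14230 CPM, yet 13880 CPM of ribosomal protein RNA against at most 10100 CPM in vehicle, and Tbr2-negative vehicle library 3 and TSA library 2 were close in these RNAs (8591 and 8085 CPM) with 9319 and 14410 CPM of ribosomal protein RNA; as these are single libraries and 3 of 10 RNAs were positive in the Tbr2-positive nuclei, no criterion was met and the explanations cannot be told apart. Malat1 made up most of this level, at 10100 ± 1910 CPM in Tbr2-positive vehicle and 5450 ± 1130 CPM in Tbr2-negative TSA. The library values and the covariate therefore followed mainly 1 RNA. Meg3 (1090 to 454 CPM) and Miat (347 to 104 CPM) fell in the Tbr2-negative nuclei, where 2 of 10 were positive, but weighed little in the sum. With this level as a covariate the ribosomal median was still 0.66 in the Tbr2-negative nuclei (0.83 without it) and 0.73 in the Tbr2-positive ones (0.82 without it), while no gene was called. Gene sets matched on genomic span and expression had medians of 0.46 in Tbr2-negative and 0.33 in Tbr2-positive nuclei, with a central 95% up to 0.56 and 0.43. The ribosomal genes had 0.84 and 0.82, so other genes of like span and expression shared part of the rise. This argues against genomic span as the whole cause, while transcript length was not matched.

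The higher level of interneuron genes in Tbr2-negative TSA nuclei may come from a different share of interneurons, from more striatal tissue in the dissection, or from regulation within cells. Striatal markers had a median of 0.43 with 9 of 12 positive (camera adjusted p = 0.0476, and adjusted p = 0.335 with an estimated correlation), and the demand for the estimated correlation was added after the preset result had been seen. The 3 negative markers were Drd1 (-0.30), Drd2 (-0.91) and Adora2a (-0.30), none of them passing. Of the positive ones, Meis2 and Ebf1 were higher in Tbr2-positive than in Tbr2-negative vehicle nuclei (511 against 315 and 30.6 against 22.6 CPM). Further interneuron markers outside the list, used in place of an earlier test that was circular, had a median of 0.31 with 6 of 9 positive (camera adjusted p = 0.0428, and adjusted p = 0.2 with an estimated correlation). Of these positive ones, Prox1 and Sox6 were also higher in Tbr2-positive than in Tbr2-negative vehicle nuclei (69.4 against 17.9 and 187 against 75.6 CPM). The explanations cannot be told apart with these markers.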

How the results depend on the processing

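The covariate for nuclear long noncoding RNA and the block within each treatment were chosen only after the result was seen. That covariate was a summed level made up mostly of Malat1. The cause of each difference between settings was not tested. Groups of 2 to 4 libraries bound every result: the smallest exact p with 3 and 4 libraries is 0.0571, so the H3K9ac tests cannot pass after adjustment, and leaving out any library of the TSA groups raises the smallest p of 0.0286 to 0.0571 by construction.

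For RNA, the TSA effect in Tbr2-positive nuclei gave 0 genes with edgeR, 177 at an adjusted p of 0.1, 1015 with DESeq2 and 364 without the low-count filter. In Tbr2-negative nuclei the 236 genes became 1382 at 0.1, 2001 with DESeq2, 944 without the filter, 401 with the groups of the contrast alone and 0 with nuclear long noncoding RNA as a covariate. The interaction gave 11 genes with DESeq2 in place of 0. Between populations in TSA the 1871 genes became 2829 at 0.1 and 3009 with DESeq2, and in vehicle no setting moved the 4303 genes by more than 1.5 times. Of 115 list tests 35 passed with the preset correlation and 0 with an estimated one. With fry, lists passed in both comparisons of the populations and none for the interaction. For the TSA effect fry passed the ribosomal protein list in both populations. It also passed the pan-neuronal and oligodendrocyte precursor lists in Tbr2-positive nuclei. Of 162 called values of named genes, 162 kept their call with DESeq2, 155 without the filter, 153 of 161 with the groups of the contrast alone and 121 to 154 with a library left out, and 0 reversed.

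For H3K9ac in Tbr2-negative nuclei the difference in peaks reversed to 822 with a -log10 q of at least 5, 2609 without TSA library 4 and 1514 without vehicle library 2, and the difference in genes with a peak was stronger with equal lists at -294 (exact permutation p = 0.0286). Between populations in vehicle the difference in peaks reversed to -3782 without Tbr2-positive library 1 and -514 without Tbr2-negative library 4. Gene ends that gained or lost a peak moved in Tbr2-positive nuclei to 116 (-log10 q of at least 5), 31 (equal lists) and 135 (overlap of 200 bp), in Tbr2-negative nuclei to 15 with the q threshold and 15 with equal lists, between populations in vehicle to 204, 214 and 174 in the same order, and in TSA to 143 with equal lists. The RNA median at ends that lost a peak under TSA in Tbr2-positive nuclei reversed to 0.22 with equal lists and 0.006 with the q threshold. At ends gained in Tbr2-positive vehicle nuclei it was stronger, at 0.80 with equal lists (permutation p = 0.0006) and 0.42 with the q threshold (permutation p = 0.0452).

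With a library left out, genes called ranged from 0 to 39 for TSA in Tbr2-positive nuclei, 0 to 677 in Tbr2-negative nuclei, 3186 to 4495 between populations in vehicle and 683 to 1953 in TSA, and lists called from 30 to 43. Differences in peaks ranged from -38010 to -27672 for TSA in Tbr2-positive nuclei, -7755 to 2609 in Tbr2-negative nuclei, -3782 to 6942 between populations in vehicle and -34063 to -23698 in TSA. In TSA the covered length ranged from -12.98 to -10.58 Mb and genes with a peak from -1326 to -1128. Gene ends gained or lost ranged from 279 to 414, 14 to 26, 139 to 207 and 323 to 408 in that order. Leaving a library out can only keep or raise this count, as fewer libraries have to meet the rule. These ranges therefore do not test its stability.

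With the replicate number as a replicate block, 13 genes passed for TSA in Tbr2-positive and 14 in Tbr2-negative nuclei and 4266 and 1844 between populations in vehicle and TSA (4823, 2326 and 0 for the interaction with a block for each number within each treatment), 141 of the 162 named values kept their call, the difference in H3K9ac peaks between populations in vehicle was -514, and in TSA the differences of -28801 peaks, -11.22 Mb and -1199 genes had an exact p of 0.125, the smallest possible with 4 pairs. The labels state no pairing, and of 13 RNA pairs with the same number 2 had a correlation above 0.1. The 5 same-number pairs of both populations within a treatment were positive (0.081 to 0.117). The values are correlations of deviations from group means, so the groups of 2 TSA libraries give 1 value, 0.117, and its mirror, -0.117. Centring also pushes the 8 pairs with different numbers towards negative values (-0.117 to -0.015), so these are no separate support. This leaves a weak hint at pairing within treatments. The 4 same-number pairs across treatments within a population were negative (-0.03 to -0.008).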

Other observations

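The tests of respiratory chain genes and of splits of the libraries were chosen only after the result was seen.

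Nuclear-encoded subunits of the respiratory chain were mostly positive under TSA, as were the ribosomal protein genes, though neither list passed with an estimated correlation. Of 84, 82 were positive in the Tbr2-negative nuclei with a median of 0.73, where 22 were called over all genes and 65 when adjusted over the list alone (camera adjusted p = 2.5e-40, and adjusted p = 0.2 with an estimated correlation). In the Tbr2-positive nuclei 80 were positive with a median of 0.56, where 0 were called over all genes and, when adjusted over the list alone, 54 were called higher and 1 lower (camera adjusted p = 1.01e-27, and adjusted p = 0.2 with an estimated correlation). The demand for an estimated correlation was added after the preset result had been seen, and a shared program cannot be told apart from a shift in RNA composition. A measure of cytoplasmic RNA in the sorted nuclei, such as the unspliced share of reads per gene, would separate these, because a shift in composition would lower that share beyond these lists.

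For the gene ends that set the populations apart in H3K9ac, the true grouping was the only 1 of 35 splits with as many. It gave 114 against at most 33 in vehicle and 296 against at most 25 in TSA. This argues against chance but does not exclude it, as 1 of 35 is the smallest share possible and was not adjusted over comparisons. For TSA in the Tbr2-negative nuclei the splits gave no argument against chance with full lists, since 12 of 35 gave as many as the 8 seen. The highest other gave 13. There the true grouping was the only 1 with as many, by a small margin, at equal list length (15 against at most 13) and with a -log10 q of at least 5 (15 against at most 11). For the RNA of the vehicle libraries the 10 splits were too few to tell, with 4303 genes in the true grouping (1 split) and 0 in the others.

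As a hypothesis, the smaller number of peaks under TSA in Tbr2-positive nuclei is consistent with a spread of acetylation that lowers the contrast of weak regions against the input, and also with a technical difference, as lists of equal length gave 31 gene ends, 15 of them among the 232 of the full lists. A library with spiked chromatin of another species and an input for each replicate would separate these, since the spread would raise the total signal over the spike while a technical loss would not. A further hypothesis, that cell share explains the rise of Dlx5, Sst and Isl1 in Tbr2-negative nuclei, could be tested by counting cells labelled for these proteins in sections of vehicle and TSA cortex, which would show more cells if the share had changed (striatal markers had a median of 0.43) and brighter cells if regulation had.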
